A study of Mus musculus with 18 samples.

How the data were processed

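RNA of the left ventricle was sequenced in 18 libraries: 5 WT, 5 cycD2 sham, 3 cycD2 TAC and 5 cycD2 Shunt. Per the labels, RNA was isolated with the RNeasy Fibrous Tissue Mini Kit and libraries were made with the TruSeq RNA v2 kit, which does not keep the strand. The deposited values are raw counts of reads per Ensembl gene, 1 table per library, and were not normalised. Per the submitters' processing notes, the tools were CASAVA 1.8.2, FastQC, STAR 2.3.0e, SAMtools 0.1.19, HTSeq 0.6.1p1 and DESeq2 1.8, with the mouse builds GRCm38 and mm10. The notes do not give the annotation release or the strand setting. Gene symbols and positions came from GENCODE M21, which matched 36602 of the 38355 identifiers; the unmatched ones held at most 0.160% of a library's counts. All counts were 0 for 12494 genes.

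The 5 summary lines at the end of each table were not counted as genes. Reads with no feature were 13.64% to 22.78% of the reads with a gene, with no feature or ambiguous between genes, and this share was highest in WT. Reads not uniquely aligned were 37.6% to 45.9% of all lines. The 10 most abundant genes took 11.0% to 16.3% of the gene counts. Mitochondrially encoded transcripts had no counts in these tables, so their list was not analysed here. The depth was 19297821 to 30594075 gene counts per library, and for genes with few counts, such as Atp2a1 in WT, counting error makes up much of the spread between libraries.

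Genes were kept with edgeR's filterByExpr (minimum count 10, by group), which left 14876, and libraries were scaled by TMM factors. A negative binomial model with 1 mean per group was fitted to all 18 libraries with edgeR 4.0.16 (quasi-likelihood F test, robust estimation) in R 4.3.3, with a biological coefficient of variation of 0.160. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 within its comparison, and its SE is the size of the log2 fold change over the square root of F. The 4 comparisons, those the series names, were cycD2 sham with WT, cycD2 TAC with cycD2 sham, cycD2 Shunt with cycD2 sham and cycD2 Shunt with cycD2 TAC. Fold changes quoted are on the log2 scale unless written as a fold, and levels are CPM, edgeR's counts scaled by library size and TMM factor, with the SD.

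Gene lists, 33 of pathways and 12 of cell types, were written before the data were examined, as were the groups, the comparisons, the tests, the rule for naming genes and the first set of other settings. Of these 45 lists, 44 were tested with camera of limma 3.58.1 at a preset correlation of 0.01 between genes, with adjustment over the 44, and again with an estimated correlation and with fry. The rule named Ccnd2, a panel of 14 genes of cardiac load, matrix and proliferation, the 6 protein-coding genes with the largest rise and the 6 with the largest fall among those called with a mean log2 CPM of at least 1 and no overlap between the groups, and up to 4 members, by smallest p, of each list past camera or with at least 3 members called in a direction. From the last of these the text gives the first few by smallest p, and it does not give every gene that the rule names. Xist, Arntl, Myl7, Nol3 and the autosomal genes of the Shunt comparison given under other observations, which lie outside this rule, were chosen after their values were seen.

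The other settings set then were DESeq2 1.42.0, limma-voom, relative log expression and upper quartile scaling, no low-count filter, a stricter one (1 CPM in 3 libraries), the replicate number as a block, estimation that is not robust, the mean of 4 Y-linked genes as a covariate, a test against 1.5-fold, each pair of groups fitted alone, and leaving out each library in turn. Settings chosen after the data were seen were the log2 difference of Arntl and Dbp as a covariate, the mean of Myl7, Myl4 and Sln as a covariate, fits to the libraries of a single clock phase, and a fit without the library labelled cycD2 TAC replicate 2 that also had the clock covariate. Whether replicate numbers pair the libraries was checked by the correlation across genes of residuals of libraries with the same number. For TAC and sham it was 0.129, 0.151 and 0.157 for replicates 1, 2 and 4, above the limit set, so the block is given there too, although only replicate 4 was most like the library of its own number. In Shunt and TAC each of the 3 was most like the library of its own number, but the correlation was 0.170, 0.139 and 0.0928, and the last missed the limit. In sham and WT and in Shunt and sham some correlations were negative, so by that limit the numbers were not taken as pairs in these 3 comparisons; the block's counts are given for all 4.

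The method was tested on simulated data of the same sizes, depths and spread. Of genes changed 2-fold, 73.9% were called in a comparison of the size of sham with WT, 64.8% for TAC with sham, 86.8% for Shunt with sham and 62.7% for Shunt with TAC. In the same runs, 6, 6, 8 and 7 genes with no change put in were called, of 14707, 14713, 14699 and 14699 genes run, the changed ones included. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.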

Results

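RNA was sequenced from left ventricles of MHC-cycD2 mice, which carry a cyclin D2 transgene expressed in heart muscle cells, and of WT mice of the same (DBA/2J x C3HeB/FeJ)F1 background. Cyclin D2 is a cell cycle protein that drives cells from G1 into S phase. The 18 libraries formed 4 groups: WT without surgery (n = 5), cycD2 sham (n = 5), cycD2 TAC (n = 3, replicates 1, 2 and 4) and cycD2 Shunt (n = 5). TAC is a constriction of the transverse aorta, which loads the ventricle with pressure, and the Shunt is an opening between aorta and vena cava, which loads it with volume. Surgery was at 8 weeks of age. The labels describe a sham operation for each procedure and do not say which of them the sham mice had. They give each library as a separate sample, so the p-values measure the spread between these samples, part of which may be technical. Any 2 libraries of a group differed by more than counting error, with a lowest chi-square of 7.08 per gene, so none duplicated another.

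Total gene counts were 20044109, 19297821, 20703651, 22713301 and 22628120 in WT replicates 1 to 5, and 23461805, 26521057, 22162960, 23254710 and 22853371 in sham replicates 1 to 5. They were 24740087, 23653603 and 23630932 in TAC replicates 1, 2 and 4, and 25929866, 23900314, 29394181, 25890914 and 30594075 in Shunt replicates 1 to 5. After the low-count filter 14876 genes were tested, and levels are given as CPM, a gene's count scaled to a common library size. The first principal component held 31.9% of the variance and the second 25.0%.

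**Figure D1:**
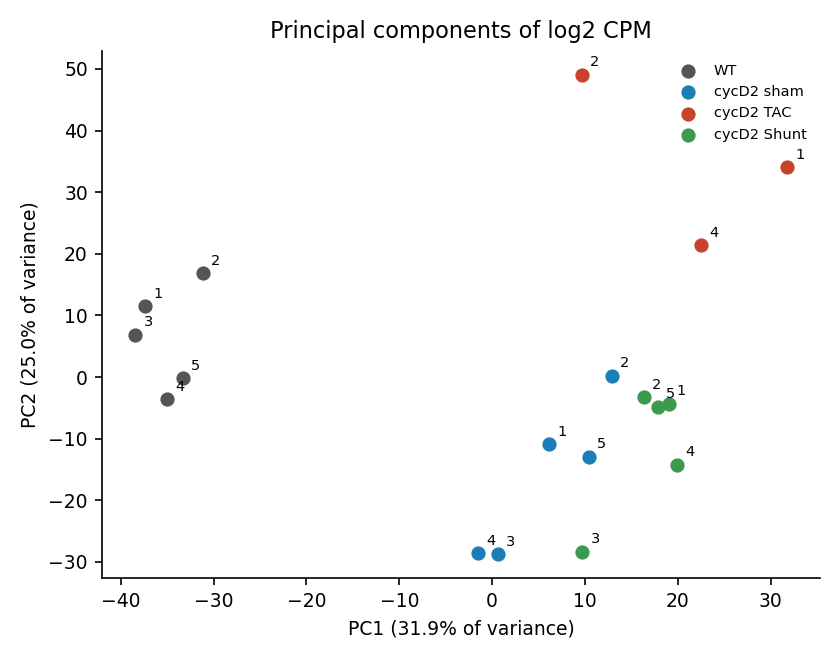
Principal components of the log2 CPM of the 2000 most variable genes, with 1 point per library and the replicate number beside it; axes give the share of variance. The first component held 31.9% and the second 25.0%.

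Ccnd2, the gene the transgene adds to (ENSMUSG00000000184, GRCm38 chromosome 6, 127125162 to 127152193), was at 172 ± 19.9 CPM (SD, n = 5) in WT and at 25496 ± 4266 CPM (SD, n = 5) in sham ventricles. Its log2 CPM was 7.14 to 7.56 in the WT libraries, 14.37 to 14.90 in sham and 14.11 to 14.44 in Shunt. TAC replicates 1 and 4 had 14.43 and 14.66. The library labelled cycD2 TAC replicate 2 had 7.83, near the WT level. Ccnd2 did not differ between the cycD2 groups past the threshold, with a log2 fold change of -0.67 for TAC against sham (adjusted p = 0.5335), -0.32 for Shunt against sham (0.8591) and 0.35 for Shunt against TAC (0.7636). Both values for TAC include replicate 2. It also enters the spread behind the Shunt against sham p, since the spread of a gene was estimated over all libraries. That p thus does not measure the spread of Shunt and sham alone. Replicates 1 and 4 lay at the top of the Shunt range and above it, so the positive sign of the 0.35 rests on replicate 2.

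**Figure D2:**
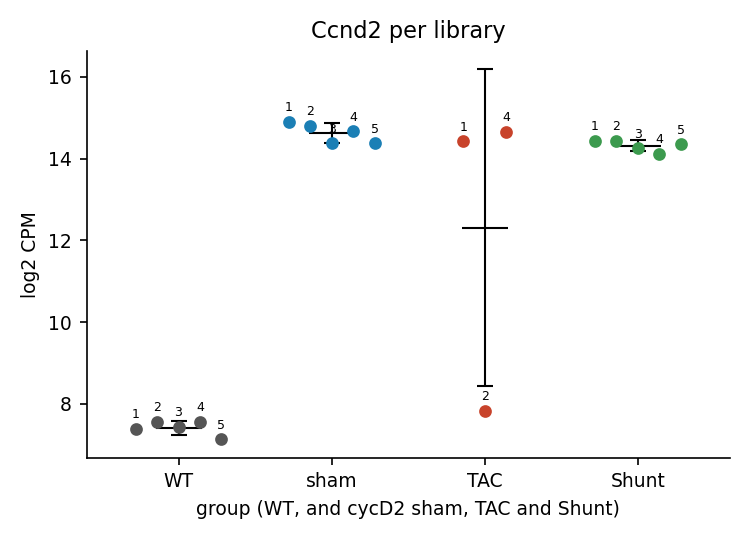
Log2 CPM of Ccnd2 in each library, by group, with the replicate number at each point and the mean and SD of each group in black. The WT libraries sat at 7.14 to 7.56 and the library labelled cycD2 TAC replicate 2 at 7.83, while the other 12 libraries labelled cycD2 were at 14.11 or above.

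Several measures split the libraries in ways the labels do not give. Xist (ENSMUSG00000086503, chromosome X, 103460366 to 103483254), which is expressed from an inactive X, had 3659 and 2644 counts in TAC replicates 1 and 2 and 3408 to 5787 in Shunt, against 4 to 13 in every other library. The Y-linked gene Ddx3y had 0 to 9 counts in those 7 libraries and 1987 to 2662 in the others, TAC replicate 4 among them. Both sexes were operated on, and the labels give no sex per sample. Sex by these genes thus followed the group except within TAC, and no sham library matched the Shunt libraries in it. The clock genes Arntl and Dbp, which peak at opposite times of day, gave a positive log2 difference (Arntl minus Dbp) in WT replicates 1 to 3, sham replicates 1 and 2 and all 3 TAC libraries. It was negative in WT replicates 4 and 5, sham replicates 3 to 5 and all 5 Shunt libraries. The atrial light chain Myl7 was at 84.9 to 319 CPM in sham replicates 2 and 5, TAC replicates 2 and 4 and Shunt replicates 2 and 4, and at 11.5 CPM or below in the other libraries.

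**Figure D3:**
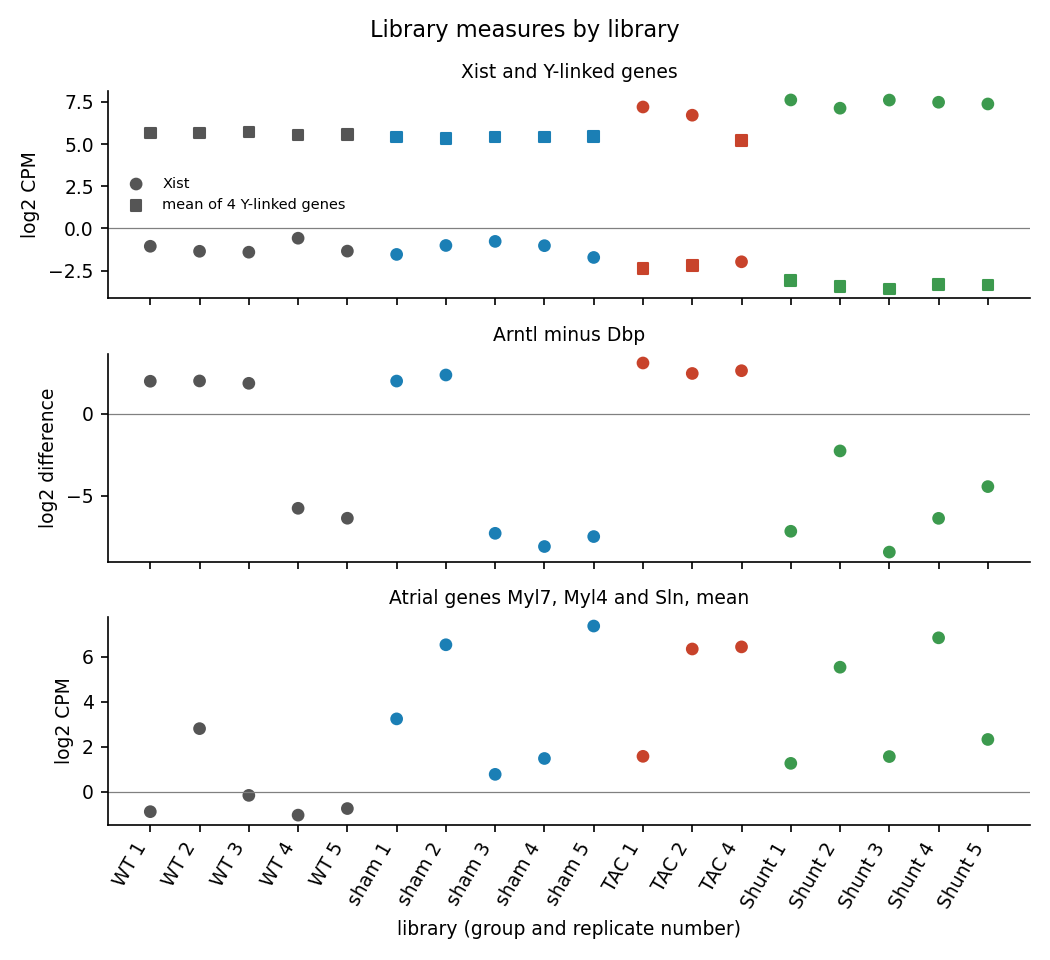
Xist and the mean of 4 Y-linked genes, the log2 difference of Arntl and Dbp, and the mean of the atrial genes Myl7, Myl4 and Sln, on a log2 CPM scale, with points for each of the 18 libraries coloured by group. Xist was high in TAC replicates 1 and 2 and in all 5 Shunt libraries, and Arntl lay above Dbp in all 3 TAC libraries and in no Shunt library.

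The comparison of cycD2 sham with WT asked how the transgenic ventricle differs from WT, and joins the genotype with the sham surgery, which WT did not have. The libraries of WT and sham also differed without overlap in the share of reads with no feature (mean 21.2% in WT, 16.4% in sham) and of reads not uniquely aligned (44.5% and 40.5%). Of 30 genes for copying DNA, 18 were higher in the transgenic ventricles, a list at an adjusted p = 0.7340 with an estimated correlation. Mcm5, a part of the helicase that opens DNA for copying, was at 24.9 ± 2.28 CPM (SD, n = 5) against 6.30 ± 1.47 in WT (n = 5). Some transcripts of skeletal muscle also rose: Atp2a1, the calcium pump of fast skeletal muscle, was at 10.6 ± 1.90 CPM against 0.406 ± 0.135. Some markers of load were lower, as the natriuretic peptide gene Nppa at 45.4 ± 6.88 CPM against 216 ± 104.

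In all, 2004 genes were higher and 2223 lower in sham than in WT, of which 294 and 375 differed at least 2-fold. Within the libraries with Arntl above Dbp (3 WT and 2 sham) 487 were higher and 652 lower, and within those with Dbp above Arntl (2 WT and 3 sham) 949 and 860. Ccnd2 had a log2 fold change of 7.21 ± 0.83 (SE, adjusted p = 3.30e-05), or 148-fold, and leaving out any 1 library gave 7.15 to 7.27. Within the libraries with Arntl above Dbp it was at 7.39 and did not pass (adjusted p = 0.0616). Both fits estimate the spread of a gene over all their groups, TAC replicate 2 with Ccnd2 near the WT level included. The SE and this p thus do not measure the spread of WT and sham alone. The largest rises by the rule for naming genes (protein-coding, a mean log2 CPM of at least 1 and no overlap between the groups) also held Atp2a1 (ENSMUSG00000030730, chromosome 7, 126445858 to 126463108) at 4.67 ± 0.40 (9.56e-07), Cpne5 at 4.50 ± 1.00 (0.0036), Myl4 at 4.31 ± 0.88 (0.0022), Tnni1, the slow skeletal troponin I of the fetal heart, at 4.18 ± 0.49 (1.43e-05) and Ptprt at 4.14 ± 0.35 (1.40e-06). Cpne5 was at 3.79 without sham replicate 5. Myl4, an atrial light chain, was at 3.62 without sham replicate 5, 5.03 without WT replicate 2 and 2.20 with the atrial covariate, which contains it. Falls named by the same rule were Bdh1 (-3.61), Cpxm2 (-3.55), Ptgds (-3.49), Tmem171 (-3.48) and Pacsin1 (-3.44).

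Of the markers of a loaded ventricle, Nppa (ENSMUSG00000041616, chromosome 4, 148000722 to 148002079) fell by 2.25 ± 0.61 on the log2 scale (adjusted p = 0.0123), Nppb (ENSMUSG00000029019, chromosome 4, 147985788 to 147987205) by 2.57 ± 0.71 (0.0137) and skeletal actin, Acta1 (ENSMUSG00000031972, chromosome 8, 123891769 to 123894751), by 3.26 ± 0.73 (0.0041). Ankrd1, a stretch-responsive gene, was at -0.91 (0.0178; 0.0538 without WT replicate 5). Both myosin heavy chains rose slightly, Myh7 by 0.47 (0.0017) and Myh6 by 0.49 (0.0045). The calcium pump gene Atp2a2 rose by 0.23 (0.0442), a call lost at 0.0521 to 0.0977 without any 1 of WT replicates 1, 2, 3 and 5 or sham replicates 3, 4 and 5. The matrix genes Col1a1 (0.20), Col3a1 (-0.16), Postn (0.17) and Ccn2 (-1.04), and Cdkn1a (0.29), Mki67 (0.42) and Pdk4 (-0.39), did not pass.

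Of the 44 gene lists tested, 12 passed camera with its preset correlation, 6 in each direction, and with an estimated correlation 0 did, while fry passed 16. In DNA replication and S phase 18 of 30 genes rose and none fell, also 18 when adjusted over the list alone (camera adjusted p = 5.77e-10; adjusted p = 0.7340 with an estimated correlation). Among these were Mcm7 (1.33), Rrm1 (0.85), Mcm5 (1.98) and Cdt1 (1.88). In G2 and mitosis 8 of 27 rose, also 8 adjusted over the list alone (4.55e-05; adjusted p = 0.7777 with an estimated correlation), led by Bub1b (1.72) and Cdc20 (1.38), whose products act at chromosome separation. Of 37 cytosolic ribosomal protein genes 15 rose, 17 adjusted over the list alone (4.55e-05; adjusted p = 0.7340 with an estimated correlation), such as Rps4x (0.35) and Rpl14 (0.44). Skeletal muscle genes rose in 6 of 9, also 6 adjusted over the list alone (5.89e-06; adjusted p = 0.3004 with an estimated correlation), with Tnni2 at 3.33 and Tnnt3 at 3.37.

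Interferon response genes fell in 15 of 25, 19 adjusted over the list alone (4.97e-05; adjusted p = 0.7340 with an estimated correlation), among them Trim30a (-0.53), Xaf1 (-0.52) and Rsad2 (-1.22). Hypoxia genes fell in 6 of 19, 9 adjusted over the list alone (0.0056; adjusted p = 0.3344 with an estimated correlation), such as Pdk1 (-0.52) and Bnip3 (-0.56). Endothelial markers fell in 7 of 16, also 7 adjusted over the list alone (0.0096; adjusted p = 0.7340 with an estimated correlation), with Pecam1 at -0.29 and Ecscr at -0.30, a call lost at 0.0913 within the libraries with Arntl above Dbp.

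The remaining 5 lists each lost their call without some single library. Fatty acid uptake and oxidation fell in 10 of 30 and rose in 2 (11 and 2 adjusted over the list alone; 0.0189; adjusted p = 0.9079 with an estimated correlation), with Etfdh at -0.48 and Acadm at -0.45, and was at 0.0545 without sham replicate 2. The TCA cycle and pyruvate dehydrogenase list fell in 10 of 25 and rose in 1, the same adjusted over the list alone (0.0405; adjusted p = 0.9584 with an estimated correlation), with Pdhx at -0.75. It was at 0.1765 without sham replicate 2 and at 0.0520 to 0.0660 without any 1 of WT replicates 1, 3 and 4 or sham replicates 1, 3 and 5. Branched-chain amino acid catabolism fell in 7 of 19, also 7 adjusted over the list alone (0.0180; adjusted p = 0.8431 with an estimated correlation), with Hibch at -0.56, and was at 0.0528 without sham replicate 1 and 0.0730 without sham replicate 2. Immediate early genes rose in 6 of 22, also 6 adjusted over the list alone (0.0180; adjusted p = 0.7340 with an estimated correlation), with Jund at 0.49, and were at 0.0638 without WT replicate 1 and at 0.0638 without sham replicate 1. Atrial markers rose in 5 of 9, with 6 rises and 1 fall adjusted over the list alone (0.0343; adjusted p = 0.7340 with an estimated correlation), as Sbk2 at 1.51. They were at 0.0627 without WT replicate 4, 0.0730 without sham replicate 2, 0.0599 without sham replicate 5 and 0.3041 with the atrial covariate, whose genes are in the list. With that covariate the TCA list was also at 0.2410 and immediate early genes at 0.0581, and with sham and WT fitted alone the TCA, branched-chain and immediate early lists were at 0.1118, 0.0744 and 0.0772. The TCA list was at 0.0528 to 0.0669 under other scaling, a stricter filter, the replicate block and the Y-linked covariate, and the atrial markers at 0.0546 under the stricter filter. Within the libraries with Dbp above Arntl the calls of these 5 lists were lost as well, at 0.0697 to 0.5831.

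Other lists held called genes without passing. Ion channels and connexins rose in 11 and fell in 5 of 25 (0.0742; 12 and 5 adjusted over the list alone), Kcnq1 at 0.84 and Kcne1 at 2.77 up and Scn4b at -2.20 down. Calcium handling fell in 7 and rose in 1 (0.0682), with Camk2b at -1.05 and S100a1 at -0.58, and its median (-0.11) and mean (0.08) differed in sign. G1 cyclins, CDKs and inhibitors other than Ccnd2 rose in 3 and fell in 1 (0.1588), with the inhibitor Cdkn2c at 1.93. The stress and fetal gene list rose in 5 and fell in 7 of 20 (0.6743), 5 and 8 adjusted over the list alone, with a median of -0.17, a mean of 0.11 and a test for a fall. Autophagy fell in 8 and rose in 2 (0.1844), angiogenic factors fell in 7 and rose in 2 (0.0682), smooth muscle and pericyte markers fell in 6 and rose in 1 (0.0803; 7 and 1 adjusted over the list alone) and mesothelial markers fell in 5 of 7 (0.0742). Collagens and other matrix genes (1 rose; 0.5252), TGF-beta signalling (2 rose, 1 fell; 0.3242), macrophage markers (0; 0.5732) and both clock lists (0 in each; 0.9179 and 0.3242) showed little.

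The comparison of cycD2 TAC with cycD2 sham asked what pressure load does in mice labelled cycD2; TAC replicate 2, with Ccnd2 near the WT level (7.83 log2 CPM), is 1 of the 3 libraries behind each TAC mean. The libraries of TAC and sham also differed without overlap in the share of reads with no feature (13.64% to 14.86% and 14.91% to 17.9%). So did the share of reads not uniquely aligned (37.69% to 39.0% and 39.07% to 41.85%). Of 20 stress and fetal genes, which a loaded ventricle switches on, 16 rose: Nppa was at 3470 ± 1335 CPM (SD, n = 3) against 45.4 ± 6.88 in sham (n = 5), and Acta1 at 6068 ± 2957 CPM against 167 ± 63.4. Of 37 matrix genes 34 rose (adjusted p = 0.1822 with an estimated correlation), Col1a1, the main fibrillar collagen, to 926 ± 406 CPM from 187 ± 75.2. Of 30 genes for the uptake and burning of fat 25 fell (adjusted p = 0.0814 with an estimated correlation), among them the transporter Slc27a1 at 93.5 ± 18.9 CPM against 234 ± 23.5. Atp2a2, the pump that returns calcium to its store, fell from 20711 ± 1039 to 12716 ± 1900 CPM.

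In all, 2440 genes were higher and 2160 lower in TAC, of which 739 and 321 differed at least 2-fold. Against the sham libraries with Arntl above Dbp alone, as in all TAC libraries, 829 were higher and 666 lower. Without the library labelled cycD2 TAC replicate 2 and with the clock difference as a covariate, 1269 were higher and 1135 lower. With the Y-linked genes as a covariate, 287 were higher and 196 lower, where the median fold change of the genes called was 0.736 of its size on the log2 scale and the median SE 1.498 times as large. These genes varied widely within TAC alone, so the fit of the covariate rests on TAC replicates 1 and 2 against replicate 4. Replicate 2 also lacked the Ccnd2 excess, so calls lost with this covariate, here and for the lists below, cannot be assigned to sex. With replicate numbers as a block, 2233 were higher and 1896 lower. By the naming rule the largest rises were Nppa at 6.26 ± 0.74 (adjusted p = 4.67e-05), or 76.5-fold, Acta1 at 5.19 ± 0.83 (3.46e-04), Nppb at 4.98 ± 0.81 (4.03e-04), Serpinb1c at 4.08 (3.78e-05), Syndig1 at 4.04 (3.15e-06) and Lman1l at 3.89 (4.88e-05). Falls named by it were the eosinophil attractant Ccl11 at -3.27 (5.08e-06), Pfkfb1 at -2.66 (1.23e-04), Sfrp5 at -2.67 (0.0027; -3.53 without TAC replicate 4) and Penk (ENSMUSG00000045573, chromosome 4, 4133531 to 4138819) at -2.63 (5.08e-04; -3.58 without TAC replicate 4). Dbp fell by 4.25 (0.0321), and the -0.21 with the clock difference as a covariate is built in, since that difference contains Dbp. Its adjusted p was 0.0513 to 0.0585 without sham replicate 3, 4 or 5, 0.1051 without TAC replicate 1, 0.1015 without TAC replicate 2 and 0.0783 without TAC replicate 4. The globin gene Hbb-bs, at -2.74 (0.0466), was at 0.0572 to 0.1052 without sham replicate 3, 4 or 5 and at 0.0851 to 0.1611 without any 1 TAC library.

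Among the markers of load, Ankrd1 rose by 2.37 (5.09e-05), Ccn2 by 3.49 (2.71e-04), Col1a1 by 2.31 (1.17e-04), Col3a1 by 2.14 (2.55e-04) and Postn by 2.88 (0.0019; 2.18 without TAC replicate 2). Myh7, the slow myosin, rose by 0.48 (0.0038), and Myh6 was at -0.54 (0.0059), a call that ended with the clock difference as a covariate (-0.37). Atp2a2 fell by 0.70 on the log2 scale (6.15e-05). The proliferation marker Mki67 rose by 1.08 (0.0264), at 0.0549 without sham replicate 1, 0.0538 without sham replicate 2, 0.0548 without sham replicate 5 and 0.1599 without TAC replicate 1. Cdkn1a, at 1.57 (0.0528), passed without sham replicate 1 (0.0406) or sham replicate 2 (0.0365). Pdk4 was at 0.26 (0.7356).

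**Figure D4:**
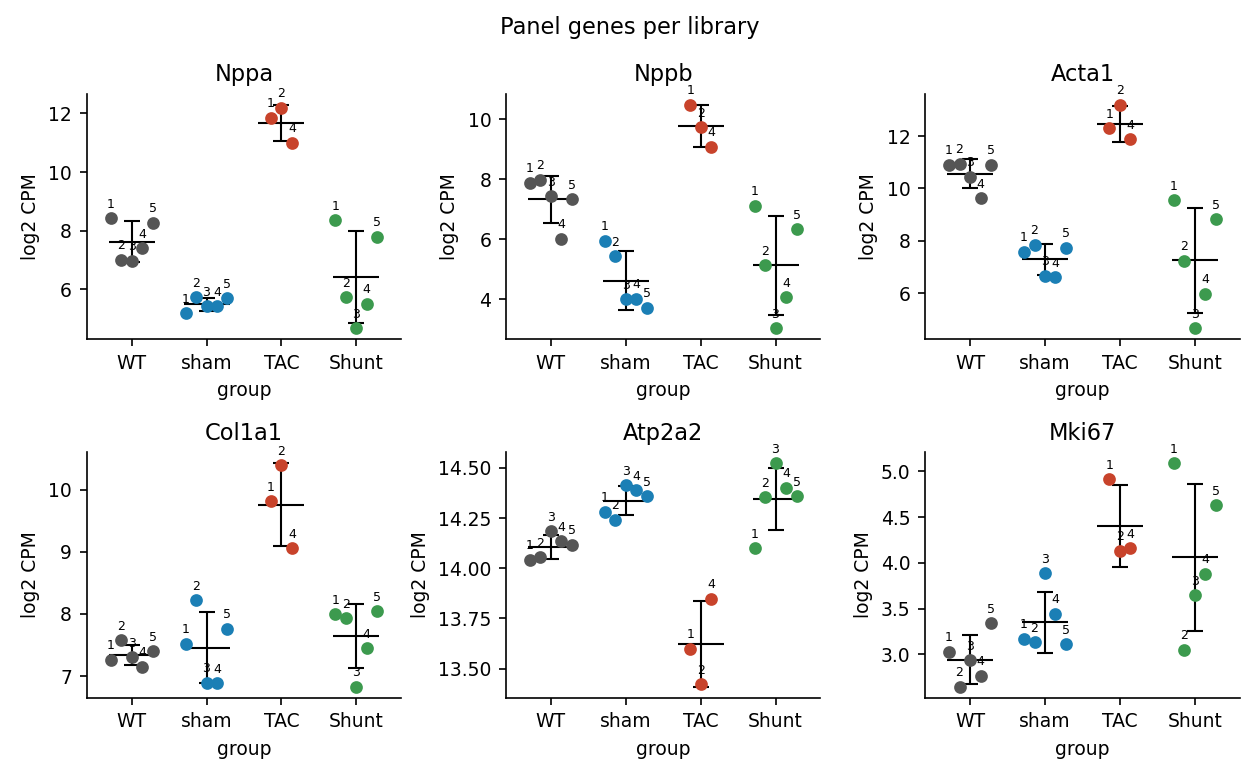
Log2 CPM of Nppa, Nppb, Acta1, Col1a1, Atp2a2 and Mki67 in each library, by group, with the replicate number at each point and the mean and SD in black. Nppa averaged 3470 CPM in TAC and 45.4 in sham, and was higher in Shunt replicates 1 and 5 than in the other Shunt libraries.

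Of the 44 lists, 21 passed camera with its preset correlation, 13 up and 8 down, and fry passed 24. With an estimated correlation 2 passed, the cardiac stress and fetal genes and the ion channels. The stress list rose in 16 of 20, with 16 rises and 1 fall adjusted over the list alone (6.13e-19; adjusted p = 0.0169 with an estimated correlation), among them Enah (1.67), Xirp2 (1.91), Uck2 (1.75) and Fhl1 (2.35). Ion channels and connexins fell in 15 of 25 and rose in 1, the same adjusted over the list alone (2.50e-08; adjusted p = 0.0430 with an estimated correlation), with Kcnj3 at -1.53 and Kcnv2 at -2.38.

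Collagens and other matrix genes rose in 34 of 37, also 34 adjusted over the list alone (5.22e-27; adjusted p = 0.1822 with an estimated correlation), such as Col8a1 (2.61) and Col15a1 (1.70). Basement membrane rose in 13 and fell in 1 of 17, the same adjusted over the list alone (2.98e-08; adjusted p = 0.1822 with an estimated correlation), with Col4a4 at 1.28. TGF-beta signalling rose in 11 and fell in 1 of 23, the same adjusted over the list alone (7.68e-07; adjusted p = 0.3369 with an estimated correlation), with Tgfb2 at 2.60 and Tgfb3 at 1.01. Matrix proteases and inhibitors rose in 13 and fell in 1 of 23, 14 and 1 adjusted over the list alone (4.06e-06; adjusted p = 0.2299 with an estimated correlation), with Mmp2 at 1.39. Fibroblast markers rose in 8 and fell in 2 of 15, 10 and 2 adjusted over the list alone (9.14e-04; adjusted p = 0.4057 with an estimated correlation), with Pi16 at 1.74 and Mfap5 at 2.28, and were at 0.1299 with the Y-linked genes as a covariate.

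Fatty acid uptake and oxidation fell in 25 of 30, 26 adjusted over the list alone (9.85e-24; adjusted p = 0.0814 with an estimated correlation), with Slc27a1 at -1.32, Decr1 at -0.96 and Hadh at -0.85. The TCA cycle and pyruvate dehydrogenase list fell in 23 of 25, 24 adjusted over the list alone (1.84e-15; adjusted p = 0.1822 with an estimated correlation), as Suclg1 at -0.68. Respiratory complexes III, IV and V fell in 22 of 30, 27 adjusted over the list alone (7.50e-11; adjusted p = 0.4057 with an estimated correlation), with Atp5a1 at -0.52. Complex I fell in 20 of 35, 23 adjusted over the list alone (3.87e-08; adjusted p = 0.4578 with an estimated correlation), with Ndufs1 at -0.47, and was at 0.3346 with the Y-linked genes as a covariate. Branched-chain amino acid catabolism fell in 17 of 19, also 17 adjusted over the list alone (1.52e-13; adjusted p = 0.1822 with an estimated correlation), with Mccc2 at -0.84.

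G2 and mitosis rose in 24 and fell in 1 of 27, 26 and 1 adjusted over the list alone (1.68e-07; adjusted p = 0.4507 with an estimated correlation), with Ncapg at 1.82, Tpx2 at 1.44 and Plk1 at 1.75, while DNA replication rose in 3 (0.4831; 2 adjusted over the list alone). Interferon response rose in 18 of 25, 21 adjusted over the list alone (1.83e-08; adjusted p = 0.4057 with an estimated correlation), with Oasl2 at 1.07. Heat shock proteins rose in 9 and fell in 1 of 18, 10 and 1 adjusted over the list alone (8.63e-04; adjusted p = 0.4126 with an estimated correlation), with Hspb1 at 1.36. Endothelial markers rose in 7 of 16, 8 adjusted over the list alone (0.0068; adjusted p = 0.4126 with an estimated correlation), with Pecam1 at 0.42. Clock genes of the PER and DBP phase fell in 6 of 10, 8 adjusted over the list alone (0.0069; adjusted p = 0.5800 with an estimated correlation), with Nr1d2 at -2.05 and Hlf at -2.42, and were at 0.6589 with the clock difference, which contains Dbp of this list, as a covariate and 0.3630 against the sham libraries with Arntl above Dbp alone, where the mean turned to 0.05 in both.

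Another 4 calls were lost without some single library, and each was lost as well with replicate numbers as a block. Smooth muscle and pericyte markers rose in 7 and fell in 1 of 14, the same adjusted over the list alone (0.0302; adjusted p = 0.4057 with an estimated correlation), with Pdgfrb at 0.72, at 0.1044 without TAC replicate 1, 0.0529 with the block and 0.0758 with the Y-linked covariate. Endoplasmic reticulum stress rose in 10 and fell in 2 of 23, the same adjusted over the list alone (0.0324; adjusted p = 0.4507 with an estimated correlation), with Pdia4 at 0.53, at 0.1131 without TAC replicate 2, 0.0520 with the block, 0.1957 with the Y-linked covariate and 0.0840 against the sham libraries with Arntl above Dbp alone. Immediate early genes rose in 4 of 22, also 4 adjusted over the list alone (0.0493; adjusted p = 0.6013 with an estimated correlation), with Egr2 at 2.55. They were at 0.1607 without sham replicate 3, 0.0632 without sham replicate 5, 0.1043 without TAC replicate 1 and 0.0529 with the block, and at 0.1523, 0.2044 and 0.0675 with the clock, Y-linked and atrial covariates, 0.0520 with upper quartile scaling and 0.4690 against the sham libraries with Arntl above Dbp alone. Oxidative stress and NRF2 targets fell in 8 and rose in 2 of 20, the same adjusted over the list alone (0.0396; adjusted p = 0.5604 with an estimated correlation), with Sod2 at -0.46. They were at 0.0891 without sham replicate 4, 0.0646 without sham replicate 5, 0.1089 without TAC replicate 1, 0.1081 without TAC replicate 4, 0.0606 with the block, 0.0558 with a stricter filter and 0.0512 with TAC and sham fitted alone. With the clock covariate their mean turned from -0.18 to 0.07 (0.6518), and against the sham libraries with Arntl above Dbp alone it was 0.06 (0.6058). Without TAC replicate 2 and with the clock covariate, the reticulum stress, immediate early, oxidative stress, fibroblast and PER and DBP phase lists were at 0.1828, 0.1667, 0.1592, 0.1025 and 0.4689.

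Of the lists that did not pass, hypoxia rose in 5 and fell in 1 (0.0721), with P4ha1 at 1.56, and p53 targets rose in 8 and fell in 4 (0.0721; 10 and 5 adjusted over the list alone), with Phlda3 at 1.24. Adrenergic and angiotensin signalling fell in 6 and rose in 2 (0.1875; 7 and 2 adjusted over the list alone), with Adra1a at -1.79 (-2.41 without TAC replicate 2). Calcium handling rose in 5 and fell in 7 (0.4526), with Hrc at -0.66 and Pln at -0.62, a median of 0.15 and a mean of -0.02. The adult sarcomere rose in 4 and fell in 7 (0.4022), glycolysis rose in 3 and fell in 4 (0.9096), with Pfkp at 1.29 and Eno3 at -0.69, and angiogenic factors rose in 7 and fell in 4 (0.5784; 7 and 5 adjusted over the list alone), with Igf1 at 1.63. Macrophage markers rose in 1 (0.2015), lymphocyte markers in 3 (0.1671; 1 adjusted over the list alone) and ribosomal proteins in 0 (0.4378). Erythroid markers fell in 1 of 6 (0.0565; 4 adjusted over the list alone).

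**Figure D5:**
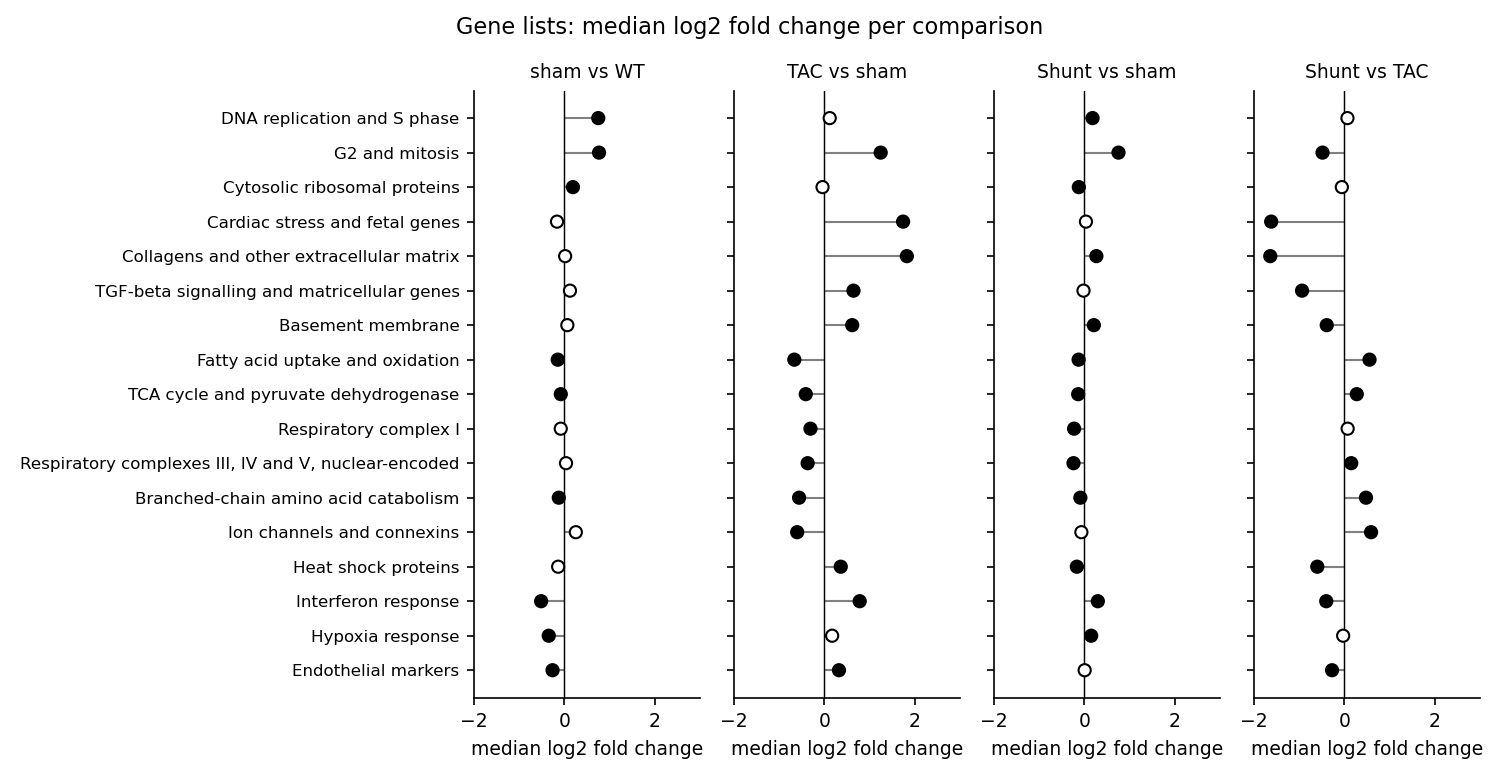
Median log2 fold change of the tested genes of 17 gene lists in each comparison, with filled points where camera with its preset correlation passed at an adjusted p under 0.05. The stress, matrix and fatty acid lists passed in TAC against sham and, in the reverse direction, in Shunt against TAC, and of these the stress list alone passed in both with an estimated correlation.

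The comparison of cycD2 Shunt with cycD2 sham asked what volume load does to the transgenic ventricle. The markers of load did not move past the spread between libraries: Nppa was at 135 ± 134 CPM (SD, n = 5) against 45.4 ± 6.88 (n = 5), Col1a1 at 210 ± 64.4 against 187 ± 75.2 and Atp2a2 at 20939 ± 2165 against 20711 ± 1039. Penk, the precursor of enkephalin peptides, fell from 13.8 ± 3.86 to 1.73 ± 0.535 CPM, and C7, a component of complement, from 19.1 ± 8.52 to 3.67 ± 1.45. Among the called genes, those with the largest fold changes were on the sex chromosomes, where the Shunt libraries had Xist and the sham libraries the Y-linked genes. By adjusted p the autosomal Hsd11b1, Dpep1 and Spon1 came first.

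In all, 16 genes were higher and 20 lower in Shunt, of which 13 were on X and 4 on Y, while 2167 of the tested genes had an unadjusted p under 0.05 and DESeq2 called 116 higher and 116 lower. With the clock difference as a covariate 30 were higher and 28 lower, and within the libraries with Dbp above Arntl (3 sham, 5 Shunt) 23 and 36. Without sham replicate 4, 7 genes were higher, and there were 8 without sham replicate 1, 10 without Shunt replicate 4 and 10 without Shunt replicate 5. With the Y-linked genes as a covariate edgeR called 0 genes, 827 had an unadjusted p under 0.05, and the median fold change of the 36 genes was 0.228 of its size on the log2 scale with a median SE 2.22 times as large. That covariate separates Shunt from sham completely, so its fit rests on the TAC libraries. By the naming rule, which leaves out Xist as not protein-coding, the largest rises were Mctp1 at 1.13 (adjusted p = 0.0233), the X-linked Kdm6a (ENSMUSG00000037369, chromosome X, 18162575 to 18279936) at 1.05 ± 0.14 (0.0013), Eif2s3x at 0.89 (0.0013) and Kdm5c at 0.82 (0.0025), Trp53inp1, a stress-induced partner of p53, at 0.82 ± 0.13 (0.0045) and Fnip2 at 0.74 (0.0153). Mctp1 was at 0.0639 to 0.0834 without any 1 of sham replicates 1, 3, 4 and 5 or Shunt replicates 1 and 5. Fnip2 was at 0.0521 to 0.0711 without any 1 of sham replicates 1, 3 and 4 or Shunt replicate 1. Its largest falls were the Y-linked Ddx3y, with 2039 to 2568 counts per sham library and 0 or 1 per Shunt library, and Eif2s3y, Uty and Kdm5d on the same chromosome. It also named Penk, which fell by 3.00 ± 0.38 on the log2 scale (0.0013), and C7, which fell by 2.39 ± 0.31 (0.0013).

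No panel gene passed: Nppa was at 1.58 (0.2502), Nppb at 0.89 (0.5812), Acta1 at 0.79 (0.6324), Ankrd1 at -0.48 (0.4172), Myh7 at -0.18 (0.4075), Myh6 at -0.16 (0.5471), Atp2a2 at 0.02 (0.9504), Col1a1 at 0.17 (0.8356), Col3a1 at 0.41 (0.5584), Postn at 0.65 (0.6002), Ccn2 at 0.77 (0.4720), Cdkn1a at 0.42 (0.7603), Mki67 at 0.86 (0.2266) and Pdk4 at 0.26 (0.8282). In simulated data of this size, 52.2% of genes changed 1.5-fold and 86.8% of those changed 2-fold were called. The changed genes were drawn at random from all tested genes, and no sex or clock phase was put in. These shares therefore need not hold for panel genes with a wide spread, as Nppa, not called at 1.58.

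Of the 44 lists, 20 passed camera with its preset correlation, 9 up and 11 down, although edgeR and limma-voom called 0 of their 459 tested members, DESeq2 called 18, and 168 had an unadjusted p under 0.05. With an estimated correlation 0 passed, and fry passed 0. The G2 and mitosis list rose, with a median of 0.76 on the log2 scale and 18 of 27 genes past the threshold when adjusted over the list alone (3.77e-11; adjusted p = 0.6223 with an estimated correlation). Complex I had a median of -0.23 (7.47e-18; 24 of 35 adjusted over the list alone), complexes III, IV and V -0.24 (5.92e-17; 19), the TCA cycle and pyruvate dehydrogenase -0.14 (7.22e-08; 1) and fatty acid uptake and oxidation -0.13 (3.96e-04; 8 falls and 1 rise adjusted over the list alone), each at an adjusted p = 0.6223 with an estimated correlation. The interferon response was at 0.30 (1.11e-06), basement membrane at 0.21 (2.25e-04; 2 adjusted over the list alone), hypoxia at 0.15 (0.0047; 3), ribosomal proteins at -0.12 (1.70e-05), heat shock proteins at -0.17 (6.42e-04) and Schwann cell markers at -0.42 (0.0032), also at an adjusted p = 0.6223 with an estimated correlation. Collagens and other matrix genes were at 0.27 (1.57e-04; adjusted p = 0.7037 with an estimated correlation). The Y-linked covariate separates Shunt from sham completely, so its fit rests on the TAC libraries and cannot part sex from volume load. With the Y-linked genes as a covariate the direction of camera's test turned for 11 of the 20 lists, with the mean of the matrix genes at -0.94 and that of fatty acid uptake and oxidation at 0.32. The mean of the glucocorticoid targets turned as well, to -0.018 (0.9129). Glycolysis (0.2998), hypoxia (0.4414), oxidative stress (0.0860), mesothelial (0.2703) and Schwann cell (0.0845) lists lost their calls with it.

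The other 8 calls each ended without some single library. DNA replication and S phase (median 0.18, 0.0097; adjusted p = 0.7715 with an estimated correlation) was at 0.0669 without sham replicate 2, 0.2237 without Shunt replicate 1 and 0.0564 without Shunt replicate 5. Glycolysis (-0.10, 0.0117) was at 0.0516 without sham replicate 4 and 0.1442 without Shunt replicate 4. Branched-chain amino acid catabolism (-0.09, 0.0048) was at 0.0901 without Shunt replicate 1. The adult sarcomere (-0.07, 0.0212) was at 0.0649 without sham replicate 4 and 0.0838 without Shunt replicate 2. Endoplasmic reticulum stress (0.10, 0.0236) was at 0.1242 without sham replicate 3, 0.1768 without Shunt replicate 3 and 0.0590 without Shunt replicate 4. Oxidative stress and NRF2 targets (-0.07, 0.0195) were at 0.1443 without sham replicate 4 and 0.0727 without sham replicate 5, where their mean turned from -0.03 to 0.014 and 0.0080. Glucocorticoid targets (0.40, 0.0122) were at 0.2237 without Shunt replicate 1 and 0.0737 without Shunt replicate 5. Mesothelial markers (1.46, 0.0342) were at 0.0954 without sham replicate 3, 0.0516 without sham replicate 4, 0.0850 without Shunt replicate 1, 0.4756 without Shunt replicate 2, 0.0826 without Shunt replicate 5 and 0.1505 under a stricter filter. With the clock covariate DNA replication was at 0.0946, and within the libraries with Dbp above Arntl the DNA replication, glucocorticoid, mesothelial and Schwann cell lists were at 0.2946, 0.2344, 0.2244 and 0.1640. The last 7 of these were at an adjusted p = 0.6223 with an estimated correlation. Stress and fetal genes (0.9612), TGF-beta signalling (0.9612), calcium handling (0.5982), ion channels (0.3666), macrophage markers (0.5982), atrial markers (0.5982) and endothelial markers (0.9748) did not pass. TGF-beta signalling had a median of -0.02 and a mean of 0.05.

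Of the genes called against sham, 19 were called in the same direction in TAC and in Shunt, 8 higher and 11 lower, of which 6 were on X. The count was 12 without any 1 of sham replicates 4 and 5 or Shunt replicates 1 and 5, and 65 without TAC replicate 4, the TAC library with Y-linked counts. Both contrasts use the same sham libraries, and with TAC tested against sham replicates 1 and 2 and Shunt against sham replicates 3 to 5 the count was 11, and 2 the other way round. The first way matched clock phase in both contrasts and the other way in neither. These counts therefore cannot tell the use of the same sham libraries from clock phase. Nol3 was called in opposite directions, at 0.27 in TAC and -0.33 in Shunt.

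The comparison of cycD2 Shunt with cycD2 TAC asked whether pressure and volume load differ in mice labelled cycD2, and its TAC means again include replicate 2, with Ccnd2 near the WT level. The share of reads with no feature did not overlap between these groups (15.03% to 19.87% in Shunt and 13.64% to 14.86% in TAC). Nppa was at 135 ± 134 CPM (SD, n = 5) in Shunt against 3470 ± 1335 (n = 3), Col1a1 at 210 ± 64.4 against 926 ± 406, and the fatty acid transporter Slc27a1 at 223 ± 12.8 against 93.5 ± 18.9. Hspb1, a small heat shock protein gene, was at 44.5 CPM against 137 ± 6.18. For comparison, sham ventricles had 45.4 ± 6.88 CPM of Nppa, 187 ± 75.2 of Col1a1, 234 ± 23.5 of Slc27a1 and 53.1 of Hspb1.

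In all, 1985 genes were higher and 2030 lower in Shunt than in TAC, of which 286 and 550 differed at least 2-fold. All TAC libraries had Arntl above Dbp and all Shunt libraries the reverse, so no comparison within a clock phase was possible. With the clock difference as a covariate 1074 were higher and 1053 lower, and 626 and 675 when the library labelled cycD2 TAC replicate 2 was also left out. Nppa was at -4.68 ± 0.70 (adjusted p = 3.30e-04; -5.32 without Shunt replicate 1), Acta1 at -4.39 (0.0012; -5.13 without Shunt replicate 1), Syndig1 at -4.39 (2.40e-06) and Nppb at -4.08 (0.0017; -4.75 without Shunt replicate 1). Of the falls the rule named, Ddx3y, Uty and Kdm5d were Y-linked, and Ddx3y had 4, 9 and 1987 counts in TAC replicates 1, 2 and 4. Kdm5d was at 0.0513 without TAC replicate 4.

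Of the 6 rises the rule named, 4 were clock genes. Dbp was at 4.46 (0.0306) and at 0.60 with the clock difference, which contains it, as a covariate, and its adjusted p was 0.0972 without TAC replicate 1, 0.1016 without TAC replicate 2, 0.0783 without TAC replicate 4 and 0.0537 without Shunt replicate 3. Per3 was at 3.21 (0.0314) and at 0.27 with that covariate, and at 0.0881 to 0.0923 without any 1 TAC library, 0.0625 without Shunt replicate 3 and 0.0526 without Shunt replicate 4. Hlf at 2.45 (0.0117) and Nr1d2 at 2.40 (0.0033) moved to 0.56 and 1.01 with it. Ucp3, a mitochondrial carrier induced by fatty acids, was at 2.54 (0.0019) and Fbp2 at 2.34 (2.40e-06).

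Of the panel, Ankrd1 (-2.85, adjusted p = 2.27e-05), Ccn2 (-2.72, 0.0018), Col1a1 (-2.14, 3.17e-04), Col3a1 (-1.73, 0.0016) and Myh7 (-0.66, 4.60e-04) were lower in Shunt, and Atp2a2 was higher (0.72, 8.23e-05). Postn was lower at -2.24 (0.0103), and at -1.53 (0.0965) without TAC replicate 2. Myh6 was higher at 0.38 (0.0464), a call lost at 0.0602 without TAC replicate 1, 0.2687 without TAC replicate 2 and 0.0674 to 0.0827 without any 1 of Shunt replicates 2 to 5. Cdkn1a (-1.15, 0.1568), Mki67 (-0.21, 0.6878) and Pdk4 (0.0041, 0.9963) did not pass.

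Of the 44 lists, 18 passed camera with its preset correlation, 7 up and 11 down, and fry passed 17. With an estimated correlation 1 passed, the stress and fetal genes, which fell in 17 of 20, also 17 adjusted over the list alone (5.50e-22; adjusted p = 0.0060 with an estimated correlation), with Xirp2 at -1.90 and Enah at -1.53. Collagens and other matrix genes fell in 33 of 37, 34 adjusted over the list alone (5.50e-22; adjusted p = 0.2857 with an estimated correlation), with Col1a2 at -1.81 and Lox at -2.97 (-2.08 without TAC replicate 2). TGF-beta signalling fell in 12 and rose in 1 of 23, 13 and 1 adjusted over the list alone (1.30e-07; adjusted p = 0.2961 with an estimated correlation), with Tgfb2 at -2.37. Matrix proteases and inhibitors fell in 13 and rose in 1 of 23, 15 and 1 adjusted over the list alone (7.35e-06; adjusted p = 0.2938 with an estimated correlation), with Mmp2 at -1.26 and Timp1 at -3.42 (-2.37 without TAC replicate 2). Basement membrane fell in 11 and rose in 1 of 17, the same adjusted over the list alone (9.49e-05; adjusted p = 0.4021 with an estimated correlation), with Nid1 at -0.69. Fibroblast markers fell in 8 and rose in 1 of 15, the same adjusted over the list alone (0.0033; adjusted p = 0.4916 with an estimated correlation), with Pi16 at -1.33, and endothelial markers fell in 5 of 16, also 5 adjusted over the list alone (0.0034; adjusted p = 0.4916 with an estimated correlation), with Ecscr at -0.47.

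Fatty acid uptake and oxidation was higher in Shunt in 25 of 30, 27 adjusted over the list alone (2.44e-19; adjusted p = 0.1641 with an estimated correlation), with Slc27a1 at 1.26 and Lpl at 0.82. The TCA cycle and pyruvate dehydrogenase list was higher in 17 of 25, 20 adjusted over the list alone (7.83e-09; adjusted p = 0.4021 with an estimated correlation), with Suclg2 at 0.56. Branched-chain amino acid catabolism was higher in 15 of 19, 16 adjusted over the list alone (1.76e-10; adjusted p = 0.2857 with an estimated correlation), with Aldh6a1 at 0.85. Ion channels and connexins were higher in 16 and lower in 1 of 25, the same adjusted over the list alone (5.65e-08; adjusted p = 0.0556 with an estimated correlation), with Kcnj3 at 1.36. Complexes III, IV and V were higher in 7 of 30, 6 adjusted over the list alone (0.0042; adjusted p = 0.7845 with an estimated correlation), with Atp5c1 at 0.41, at 0.1004 without TAC replicate 1 and 0.0889 without TAC replicate 2. Heat shock proteins were lower in 14 and higher in 1 of 18, the same adjusted over the list alone (5.81e-08; adjusted p = 0.2857 with an estimated correlation), with Hspb1 at -1.62 and Hspb6 at -0.91.

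The interferon response was lower in 9 of 25, 10 adjusted over the list alone (4.96e-04; adjusted p = 0.6554 with an estimated correlation), with Oasl2 at -0.69 and Isg15 at -0.79, and was at 0.0849 with the clock difference as a covariate. Clock genes of the PER and DBP phase were higher in 6 of 10, 8 adjusted over the list alone (1.81e-04; adjusted p = 0.4916 with an estimated correlation), at 0.2788 with that covariate. Immediate early genes were lower in 3 of 22, also 3 adjusted over the list alone (0.0171; adjusted p = 0.6306 with an estimated correlation), with Egr2 at -3.13, at 0.0534 without TAC replicate 1. Glucocorticoid targets were higher in 4 and lower in 1, the same adjusted over the list alone (0.0381; adjusted p = 0.6554 with an estimated correlation), with Pik3r1 at 1.48, and were at 0.0967 without TAC replicate 1, 0.1819 without TAC replicate 4, 0.1711 without Shunt replicate 1 and 0.0855 without Shunt replicate 5. G2 and mitosis passed downward (0.0381; adjusted p = 0.8367 with an estimated correlation) although its 1 called gene, Cenpf, was higher at 1.23 (0.0184) and 0 were called when adjusted over the list alone. It was at 0.5330 without TAC replicate 1, 0.0790 without TAC replicate 4, 0.1720 without Shunt replicate 2, 0.1212 without Shunt replicate 3 and 0.0822 without Shunt replicate 4, and Cenpf at 0.1055 without TAC replicate 2 and 0.0516 without TAC replicate 4. G2 and mitosis was at 0.1165 with the Y-linked covariate and 0.0784 with Shunt and TAC fitted alone. Immediate early genes and glucocorticoid targets were at 0.1112 and 0.3075 with the clock covariate, and glucocorticoid targets at 0.2338 with the Y-linked and 0.0518 with the atrial covariate. Without TAC replicate 2 and with the clock covariate, fibroblast markers were at 0.3096, matrix proteases and inhibitors at 0.0536, complexes III, IV and V at 0.3592, the interferon response at 0.3592, immediate early genes and the PER and DBP phase at 0.1604 and glucocorticoid targets at 0.0830.

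Of the lists that did not pass, endoplasmic reticulum stress was lower in 9 and higher in 3 (0.2598), p53 targets lower in 8 and higher in 3 (0.3134; 9 and 6 adjusted over the list alone), complex I higher in 4 (0.1123; 1 adjusted over the list alone) and DNA replication lower in 1 (0.6754; 0 adjusted over the list alone). Smooth muscle and pericyte markers were lower in 4 and higher in 1 (0.0549; 5 and 1 adjusted over the list alone), macrophage markers lower in 4 (0.0914) and erythroid markers higher in 3 of 6 (0.0501; 5 adjusted over the list alone). Calcium handling was higher in 6 and lower in 4 (0.6250; 7 and 4 adjusted over the list alone), with a median of -0.17, a mean of -0.03 and a test for a rise. The adult sarcomere was higher in 6 and lower in 6 (0.9490), with a median of -0.06 and a mean of 0.04. Antigen presentation (0; 0.2347), neutrophil (0; 0.9767), adipocyte (1 lower; 0.7447) and Schwann cell (1 lower; 0.6250) markers showed little, and the adipocyte (median 0.39) and mesothelial (median 0.74, 0.7541) markers had a test for a fall.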

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

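Tests of a swap with WT, of the promoter and of the share of X- and Y-linked genes, and the alternatives with a clock or atrial covariate, were chosen after the result was seen.

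In the library labelled cycD2 TAC replicate 2, Ccnd2 was near the WT level (7.83 log2 CPM), against 14.43 and 14.66 in the other TAC libraries. Over 3152 other genes that differed from WT in both sham and Shunt, the WT mean was set to 0 and the transgenic mean to 1. This library lay at 0.31 and the other TAC libraries at 0.91 and 0.87, a gap of 0.558 to the nearer one. The gap exceeded the limit set before for an animal without an active transgene. The library still lay above the WT libraries (-0.10 to 0.12), so it was between WT and the transgenic mean. A swap with a WT library of this series is argued against, since the highest WT library had Ccnd2 at 7.56. Loss of activity of the MHC promoter is argued against too, since the Myh6 distance between this library and the other TAC libraries was 0.0894 of the Ccnd2 distance on the log2 scale. A wrong genotype or label, including a WT animal with TAC from outside these libraries, stays open, and may explain the level.

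The 4600 genes called between TAC and sham could in part follow clock phase, sex or the library without Ccnd2 excess. Against the sham libraries of the same phase alone, the median ratio of the log2 fold changes was 0.894, which argues against phase as the whole cause. The Shunt libraries, which had Xist as TAC replicates 1 and 2 did, moved from sham by a median of 0.172 of the TAC change, which argues against sex as the whole cause, and without the library labelled cycD2 TAC replicate 2 the ratio was 0.913. Of the 56 splits of these 8 libraries only the real one gave as many genes. Replicate numbers may pair the libraries, since same-number correlations were above the limit set, although only replicate 4 was most like its own number. If they do, the 8 splits that part each pair (highest other 10) are too few for a share under 0.05. The highest of all others (1961) set sham replicates 3 to 5 apart from the rest, as clock phase does, and pressure load stays open beside part contributions of phase and sex.

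Of the 36 genes called between Shunt and sham, 47.2% were on X or Y against 3.45% of all genes tested (Fisher's exact test, one-sided p = 4.98e-16), as a difference in sex would give. Of the 19 autosomal genes, 89.5% (17) also differed in the Shunt direction between the TAC libraries with Xist and the 1 with Y-linked counts. Sex and volume load cannot be told apart for these 19, since every Shunt library had Xist and no sham library did, and a single TAC library had Y-linked counts. Clock phase is argued against, with a median ratio of 1.06 against sham libraries of the same phase. Of 100 splits (the real one and a random draw of the others), 2 gave at least 36 genes. These were the real one and another with 114 (Shunt replicates 1, 2 and 5 with sham replicates 1 and 2). That share is under 0.05, but the other split gave more genes than the real one. The count alone thus excludes neither chance nor a structure within the groups.

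For sham and WT, 100 splits were run, the real one and a random draw of the others. Only the real one gave 4227 genes or more and the highest other gave 812, so chance is argued against if the libraries are unpaired. If replicate numbers pair them, the 14 splits run that part each pair (highest other 0) are too few for a share under 0.05. The split with 812 joined WT replicates 1 to 3 with sham replicates 1 and 2, as clock phase does. Within the phases 487 and 949 genes were higher. For Shunt and TAC, only the real split of 56 gave 4015 or more, so chance is argued against if the libraries are unpaired. The highest other, which joined Shunt replicates 1 and 5 to the TAC libraries, gave 2530. If replicate numbers pair these libraries, the 8 splits that part each pair (highest other 0) are too few for a share under 0.05.

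The changes of TAC and Shunt from sham differed for 4015 of 14876 genes by the direct test between them, and for 98 of the 142 genes named in the text. The naming rule chose some of these 142 by that same test, which raises their share. The share of reads that the counter left as ambiguous between genes, which is outside the gene counts, averaged 1.96% in TAC against 1.52% in sham (n = 3 and 5, exact permutation test of unpaired libraries, two-sided p = 0.0357). That p is the lowest that groups of these sizes can give. The shares of reads with no feature and not uniquely aligned also differed without overlap between TAC and sham.

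Of 444 groups of 5 libraries tested for a single distant library, 20 exceeded Dixon's critical value for the gap over the range, and chance flags about 1 in 20 groups. In WT these were Jund, lowest in replicate 1 (0.766), Myl4 and Sln, highest in replicate 2 (0.756 and 0.772), Spon1, highest in replicate 1 (0.746), Tgfb2, lowest in replicate 3 (0.742), Tnnt3, lowest in replicate 4 (0.764), Trim30a, highest in replicate 3 (0.728), and the share of the 10 most abundant genes, highest in replicate 4 (0.802). In sham they were Cdt1, Mcm5 and Tpx2, lowest in replicate 2 (0.888, 0.732 and 0.730), Jund, lowest in replicate 3 (0.729), Lvrn, lowest in replicate 4 (0.717), and Sbk2, lowest in replicate 1 (0.781). In Shunt they were Camk2b, Mmp2 and Tgfb2, lowest in replicate 3 (0.814, 0.835 and 0.773), Pik3r1, lowest in replicate 2 (0.748), Rpl14, highest in replicate 1 (0.869), and Tnni1, highest in replicate 4 (0.783). No explanation was tested for them.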

How the results depend on the processing

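The clock and atrial covariates, the fits within a clock phase and those that joined a left-out library with a covariate were chosen after the data were seen. Over all settings, 9365 values of named genes counted as the same. That label also takes in sign changes with no call in either setting, and values without an adjusted p. Another 1074 no longer passed, 9 newly passed and 3 reversed with a call in either setting. For lists past camera 1283 kept the test's direction and passed, 222 kept it and no longer passed, and in 11 it reversed. Among the 222 the list mean changed sign for glucocorticoid targets with the Y-linked covariate (-0.018, Shunt against sham), for oxidative stress and the PER and DBP phase in TAC against sham with the clock covariate, which holds Dbp itself (0.072 and 0.048), and within the libraries with Arntl above Dbp (0.055 and 0.046), and for oxidative stress in Shunt against sham without sham replicates 4 (0.014) or 5 (0.0080). DESeq2 gave 116 higher and 116 lower for Shunt against sham and 137 shared with TAC. The Y-linked covariate gave 287 and 196 for TAC against sham, 0 and 0 for Shunt against sham and 0 shared, reversed Kdm5c (-0.15) and the Shunt means of matrix (-0.94), basement membrane (-0.10), fatty acid (0.32), TCA (0.17), complex I (0.24), complexes III to V (0.26), branched-chain (0.18), sarcomere (0.20), reticulum stress (-0.035), interferon (-0.074) and ribosomal (0.10) lists; it separates Shunt from sham completely, so that fit rests on the TAC libraries. The 1.5-fold test, stricter by construction, gave 137 and 219 (sham against WT), 413 and 187, 1 and 11 (Shunt against sham), 117 and 255, and 4 shared. Shunt and TAC fitted alone gave 1308 higher. Camera with an estimated correlation passed 0, 2, 0 and 1 lists and fry 0 for Shunt against sham. The clock covariate gave 30 higher for Shunt against sham and 1074 and 1053 for Shunt against TAC. Libraries with Arntl above Dbp, fewer by construction, gave 487 and 652 for sham against WT, 829 and 666 for TAC against sham, and Tef at 0.13. Ccnd2 was there at 7.39 (adjusted p = 0.0616) for sham against WT, with TAC replicate 2 in the estimate of its spread. Those with Dbp above Arntl gave 949 and 860 for sham against WT and 36 lower for Shunt against sham. Without TAC replicate 2 and with the clock covariate there were 1269 and 1135 for TAC against sham, 626 and 675 for Shunt against TAC, and Myh6 for Shunt against TAC at -0.023. With sham replicates split between the contrasts, clock phase matched and then mismatched, 11 and 2 genes were shared. Unless given, the cause was not tested.

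Leaving out each library gave, for higher, lower and lists, 1556 to 2062, 1771 to 2027 and 8 to 14 for sham against WT (Ccnd2 7.15 to 7.27), 1633 to 2600, 1624 to 2324 and 18 to 23 for TAC against sham, 7 to 18, 14 to 23 and 16 to 21 for Shunt against sham, 1346 to 2158, 1357 to 2198 and 15 to 21 for Shunt against TAC, and 12 to 65 shared. The replicate block gave 2023 and 2219 for sham against WT, 2233 and 1896 (17 lists) for TAC against sham, 19 and 24 for Shunt against sham and 1663 and 1730 for Shunt against TAC, with 26 shared. Depth limits the genes with few counts.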

Other observations

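The share of genes that moved back and the chromosome windows were tested as planned before their values were seen; the genes in the next paragraph were chosen after theirs.

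Of the 19 autosomal genes called between Shunt and sham, 15 fell. Hsd11b1, which makes active glucocorticoid, was at -1.23 (adjusted p = 1.34e-04) in Shunt and -0.75 in TAC, the peptidase gene Dpep1 at -1.41 (1.39e-04) and -0.54, the matrix gene Efemp1 at -1.16 (0.0102) and -1.72, and the chemokine Ccl11 at -1.26 (0.0187) and -3.27. The chondromodulin gene Cnmd was at -2.48 (0.0243) and -1.72, Lvrn at -2.49 (0.0021) and -2.93, Cpne7 at -1.74 (0.0022) and -1.34, and the interferon-inducible Ifi205 at -1.51 (0.0013) and -1.47, all called in both. Spon1, a matrix gene, was at -0.86 (1.73e-04) in Shunt and -0.03 in TAC. Nppa was at 8.37 and 7.80 log2 CPM in Shunt replicates 1 and 5 and at 4.68 to 5.74 in the other Shunt libraries, and Nppb at 7.11 and 6.32 against 3.03 to 5.12.

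Between TAC and sham and between Shunt and sham, 19 genes were shared in the same direction, 8 higher and 11 lower, against 2.62 and 2.90 for independent calls; the calls are not independent, as both use the same sham libraries. Over the tested genes with a mean log2 CPM of at least 1, the log2 fold changes had a correlation across genes of 0.356. In 50 simulations with the shared sham libraries and no effect put in it was 0.432. The covariance was 0.0583 against 0.0135 (at most 0.0163), and genes are not independent replicates. No sex or clock phase was put into the simulations, so the higher covariance cannot be assigned to load. With sham replicates 1 and 2 for TAC and 3 to 5 for Shunt the correlation across genes was 0.397, and -0.04 the other way round. The first way matched clock phase in both contrasts and the other way in neither, so phase may account for the drop.

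A hypothesis was that pressure load takes part of the genotype difference back. Of 4226 genes called between sham and WT, Ccnd2 left out, 67.0% had the opposite sign in TAC minus Shunt. Without the library labelled cycD2 TAC replicate 2 the share was 55.4%, between the limits of 55% and 60% set before. Of the genes also called between Shunt and TAC, 1090 of 1363 had the opposite sign, and 618 of 945 without TAC replicate 2. The limits were set for the share of all genes called between sham and WT, not for these. All TAC libraries had Arntl above Dbp and all Shunt libraries the reverse, and sex differed in part between them. These shares therefore cannot tell pressure load from clock phase or sex. A partial return is thus neither shown nor argued against.

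Another hypothesis was that a block of chromosome carried along with the transgene may hold the largest differences between sham and WT. Genes without a known position and Ccnd2 were left out, which left 663 genes that differed at least 2-fold. The densest 10 Mb window (chromosome 17, 20000001 to 30000000) held 12 of them. Of 1000 random draws of as many genes, 61.6% had a window with at least as many. A block that holds many of these genes is thus argued against, and a block with few is not excluded.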
